A study of Mus musculus with 8 samples.

How the data were processed

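RNA was measured by stranded mRNA sequencing of the hippocampus of 2-month-old C57BL/6 mice, in 4 samples of the control genotype (both Sumo2 alleles flanked by loxP sites) and 4 of the conditional knockout genotype (the same alleles with Emx1-Cre), per the labels. Cre is a recombinase that removes DNA between loxP sites, and Emx1-Cre acts in part of the cells of the hippocampus, mainly excitatory neurons and glia of the dorsal forebrain lineage. The labels give no sex, litter, batch or pairing beyond a replicate number, and do not say that the samples came from separate animals. The p-values therefore measure the spread between these samples, which may be technical.

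The submitters' processing notes name Trim Galore, cutadapt, STAR, HTSeq and DESeq2, without versions. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. The authors' deposited table lists, per the file headers, a log2 fold change of knockout over wild type, a test statistic, a p-value and an adjusted p-value for each gene, with a flag for protein-coding genes. The test statistic is a score that the authors deposited beside the log2 fold change, read here as a Wald statistic in units of the standard error. The table also holds 8 columns of normalized values per sample. Their names match none of the sample labels, so they were mapped to no sample or group and were used in no step. Depth per library, values per sample and standard deviations were not analysed here, and the precision of each gene is known only through its standard error.

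The design fixed before the data were examined called for a gene-level model of the samples. It also set that, where only the authors' comparison could be used, their values would be described and no own gene-level test run. That was done. Standard errors were taken as the log2 fold change divided by the statistic, and 95% intervals were made from them with a normal distribution. The 2-sided normal p-values of the statistics differed from the deposited p-values by at most 2.8e-15, and Benjamini-Hochberg values over the 17171 genes differed from the deposited adjusted p-values by at most 9.6e-15. A gene was called at an adjusted p under 0.05. Identifiers were matched to GENCODE M21, on genome build GRCm38, for coordinates only. Of the identifiers, 16955 matched and 216 did not. For 34 symbols there were 2 identifiers, and gene lists kept the one in GENCODE M21.

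A total of 44 gene lists were fixed before the data were examined, and a list needed at least 5 measured members. They were tested with cameraPR of limma 3.58.1 in R 4.3.3, 2-sided, on the authors' statistics, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. This test was chosen after the content of the table was known, in place of a test on library values. A correlation could not be estimated without library values, so a correlation of 0.05 was also run. Counts of called members are given over all genes and, where it differs, adjusted over the list alone. In 100 sets of statistics simulated without any shift for the 17171 genes, 2 of 4400 list calls were made. The simulated genes were independent, so these sets cannot show how correlation within a list affects the calls. With the oligodendrocyte list shifted by 1 unit of the statistic it was called in 87 of 100 sets, and with a shift of 0.5 in 11. The adjustment was tested on simulated data for the same comparison over 17171 genes. It recovered 137 of 200 genes changed by a log2 value of 0.5, and 169 of 200 genes changed by 1. False calls numbered 8 (5.52% of the calls) with a change of 0.5 and 7 (3.98%) with a change of 1.

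Named genes followed a rule fixed beforehand. It takes Sumo2, Sumo3, the 12 largest log2 fold changes in each direction among called genes with a regular symbol and adequate expression, the 5 smallest p-values in each direction, and up to 3 members with the smallest p-value from each list. Since expression columns were not used, a standard error at or below the median of all genes, 0.0940, replaced the expression criterion. That change was made after the table was seen. A further gene that the rule names is not reported here. Ttyh2, Gfap, Pdgfra, Pcdh1, Pcdhac1, Pcdhgc4, the second identifier of Atf7ip and the single genes of the families fall outside the rule and were chosen after their values were seen. For 74 genes, the share of 50-base windows of their annotated coding transcripts that occur exactly in transcripts of other genes was counted. It measures reads that sequence alone cannot assign to 1 gene. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered other sets of genes for the adjustment, other thresholds, and other settings of the list test.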

Results

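The series compared the hippocampus of control mice with that of mice in which Sumo2 was targeted in Emx1-Cre expressing cells, with 4 samples per genotype. The question was how deletion of Sumo2, which encodes a small ubiquitin-like modifier attached to other proteins, changes gene expression. The authors' deposited table gives the comparison for 17171 genes, 15416 of them listed as coding. All values below are the authors' log2 fold changes of knockout over control with the standard error (SE) derived from their statistic. The median SE in the authors' deposited table was 0.0940, with quartiles of 0.0610 and 0.226.

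Sumo2 itself was not lower in the group labelled knockout. The authors' deposited table gives Sumo2 (ENSMUSG00000020738, chromosome 11, 115523102 to 115536276, GRCm38) a log2 fold change of 0.42 (SE 0.252, 95% interval -0.07 to 0.92, adjusted p = 0.761). The targeted gene therefore does not check the genotype labels, and which part of the gene was removed is not given in the sources used here. Of its 50-base windows, 29.1% occur in transcripts of 14 other genes, so sequence alone cannot assign some of its reads. Whether counting dropped or kept such reads cannot be told from this share. Directions are for these reasons given for the group labelled knockout. Sumo3, a close relative of Sumo2, was higher in the authors' deposited table by 0.70 (SE 0.0934, 1.62-fold, adjusted p = 1.1e-10), with 9.19% of its windows shared. Of 27 measured SUMO pathway genes, Sumo3 was the 1 called, over all genes and adjusted over the list alone.

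The gene next to Sumo2 fell. Hn1 (ENSMUSG00000020737, chromosome 11, 115497353 to 115514387), also known as Jpt1, lies 8714 bases from Sumo2 on the same strand. Its log2 fold change in the authors' deposited table was -0.54 (SE 0.0552, adjusted p = 3.2e-19), the smallest p-value of any lower gene. Of the 62 other genes within 1 Mb of Sumo2, 1 was called, Ttyh2, at -0.42 (SE 0.102, adjusted p = 0.00514) in the authors' deposited table. Ttyh2 was outside the naming rule and was singled out after its value was seen. The median of those 62 genes was -0.01. None of the 25 other genes within 1 Mb of Emx1 was called in the authors' deposited table, and Emx1 itself stood at -0.27 (SE 0.112, adjusted p = 0.352). The list fixed beforehand as neighbours of Emx1 held 24 measured genes, of which 16 lie in that window by the annotation. Its 1 called member, Prdm8 at 0.33 (SE 0.0617) in the authors' deposited table, lies on chromosome 5.

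**Figure D1:**
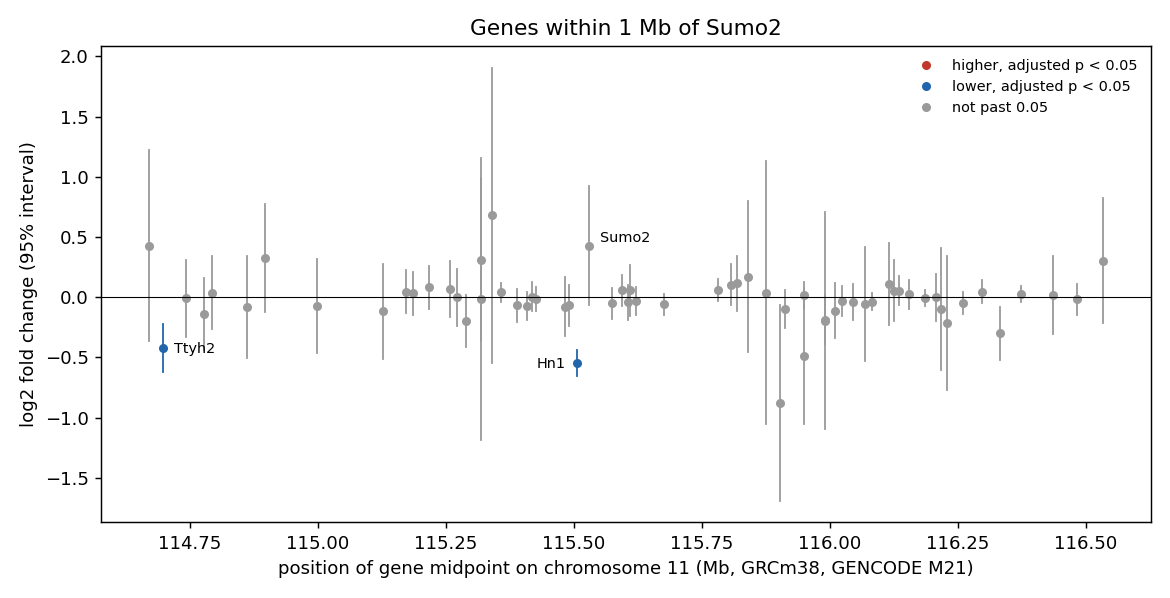
Log2 fold change (labelled knockout over control) of each gene within 1 Mb of Sumo2, placed at its midpoint on chromosome 11, with 95% intervals from the authors' deposited table. Hn1 lies at -0.54 beside Sumo2 at 0.42, and Ttyh2 is the only other called gene.

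In the authors' deposited table, 257 of 17171 genes passed an adjusted p of 0.05, 166 higher and 91 lower in the group labelled knockout. The share of higher calls was 64.6% (exact binomial 95% interval 58.4 to 70.4, which treats genes as independent). This share rests on the ratio of knockout over wild type in the file header. Were that ratio turned round, 35.4% of the calls would be higher. An unadjusted p under 0.05 was reached by 1438 genes, against 859 expected by chance. Changes were mostly small, with a median log2 fold change of 0.43 among higher and -0.31 among lower calls in the authors' deposited table. A change of 2-fold or more was seen for 24 higher and 2 lower genes. With a fold of at least 1.5 required, 67 genes remained, 56 higher and 11 lower. Calls with an SE above 0.25 were 16 higher and 1 lower, against 150 and 90 at or below it (Fisher's exact test, p = 0.00742). That test also treats genes as independent, and the cause of the difference was not tested.

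**Figure D2:**
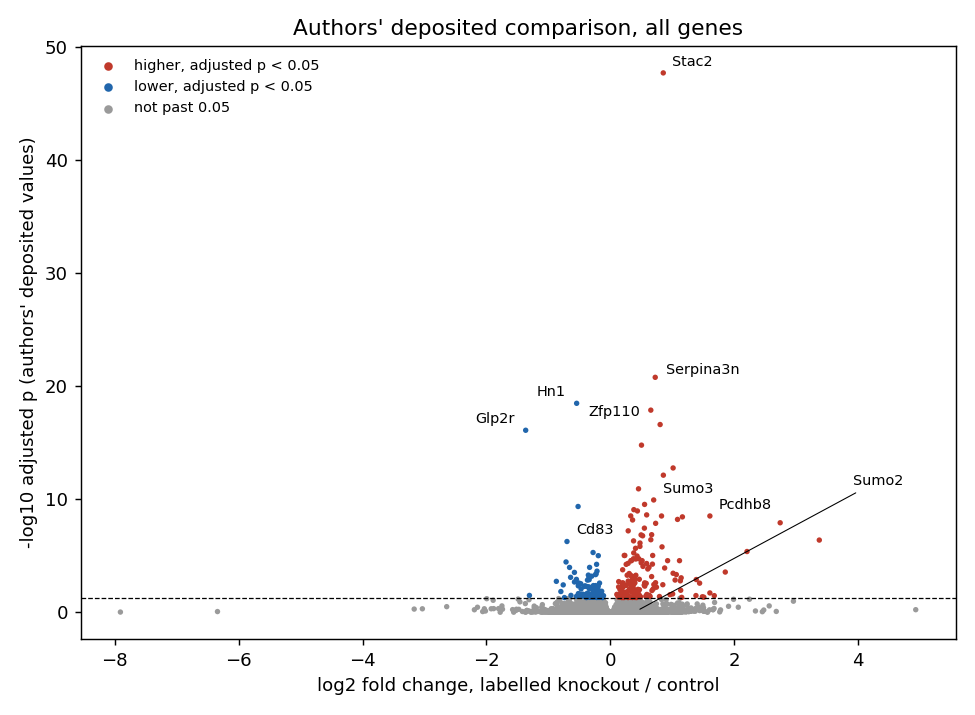
Log2 fold change (labelled knockout over control) against -log10 adjusted p for the 17171 genes of the authors' deposited table, with the dashed line at an adjusted p of 0.05. Stac2 has the smallest adjusted p (1.8e-48), and Sumo2 lies below the line.

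Stac2, an adaptor of voltage-gated calcium channels, had the smallest p-value of all genes, at 0.85 (SE 0.0559, 1.81-fold, adjusted p = 1.8e-48) in the authors' deposited table. Serpina3n, a secreted protease inhibitor raised in reactive astrocytes, was higher by 0.72 (SE 0.0694, adjusted p = 1.6e-21). The zinc finger gene Zfp110 was higher by 0.65 (SE 0.0673, adjusted p = 1.3e-18), and Atf7ip, a partner of the histone methyltransferase SETDB1, by 0.50 (SE 0.0565, adjusted p = 1.6e-15). Atf7ip has a second identifier in the authors' deposited table, at 0.44 (SE 0.0611). The noncoding 2810055G20Rik stood at 0.80 (SE 0.0857, adjusted p = 2.4e-17). The other genes with the largest rises by the naming rule, between 0.48 and 0.59 in the authors' deposited table, were Nfatc2, Slc5a5, Parp12, Car4, Ryr1, Cyp4f15 and Dpyd. Nfatc2 is a calcium-regulated transcription factor, Slc5a5 the sodium iodide symporter and Ryr1 a calcium release channel.

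Among lower genes, Glp2r, the receptor of glucagon-like peptide 2, fell the most of those with the smallest p-values, to -1.37 (SE 0.148, adjusted p = 7.7e-17) in the authors' deposited table. Skida1 stood at -0.52 (SE 0.0716, adjusted p = 4.3e-10), and Cd83, an immunoglobulin family surface protein, at -0.70 (SE 0.115, adjusted p = 5.4e-07). Ppp1r16b, a regulatory subunit of protein phosphatase 1, was at -0.28 (SE 0.0490, adjusted p = 5.1e-06). The other genes with the largest falls by the naming rule lay between -0.37 and -0.30 in the authors' deposited table. They were Rhog, Carhsp1, Fstl4, Rgs8, Nmral1, Arrdc3, Chrm3, Ptgs1, Rasd2 and Olig1. Chrm3 is a muscarinic acetylcholine receptor and Ptgs1 a cyclooxygenase.

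Oligodendrocyte markers were lower as a group. All 22 measured markers had a negative log2 fold change in the authors' deposited table, with a median of -0.40 (limma cameraPR, adjusted p = 2.9e-24, and 2.6e-14 at a correlation of 0.05). Of these, 6 were called over all genes and 20 adjusted over the list alone. Ermn, a cytoskeletal protein of myelinating cells, stood at -0.55 (SE 0.121), Tspan2 at -0.48 (SE 0.112) and Gpr37, a G protein-coupled receptor, at -0.37 (SE 0.101) in the authors' deposited table. Markers of oligodendrocyte precursors had a median of -0.11 over 15 genes (limma cameraPR, adjusted p = 9.1e-04, 0.0130 at a correlation of 0.05, and 0.218 with log2 fold changes in place of statistics). Of these, 2 were called, Olig1 at -0.30 and Enpp6 at -0.64, and 5 adjusted over the list alone. Enpp6 marks newly forming oligodendrocytes, and Pdgfra, the receptor that marks the precursors, stood at -0.09 (SE 0.0746, adjusted p = 0.978) in the authors' deposited table.

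Protocadherins of the beta cluster on chromosome 18, cell surface proteins expressed in different combinations by single neurons, were higher. The list of clustered protocadherins held 57 genes, of which 23 were measured, 21 of them Pcdhb genes, so the alpha and gamma clusters were hardly covered. Of the measured members 9 were called, each a Pcdhb gene, and 11 adjusted over the list alone, Pcdhgc4 among them (median 0.26, limma cameraPR, adjusted p = 1.1e-20, and 4.1e-12 at a correlation of 0.05). Pcdhb8 (chromosome 18, 37355121 to 37358604) had the largest rise, 1.61 (SE 0.231, 3.04-fold, adjusted p = 3.0e-09), in the authors' deposited table. Pcdhb18 stood at 0.65 (SE 0.106) and Pcdhb19 at 0.51 (SE 0.0956). Between 3.09 and 9.52% of the 50-base windows of the 9 called genes occur in other genes. The other measured members, Pcdhac1 at 0.08 (SE 0.0448, adjusted p = 0.759) and Pcdhgc4 at 0.11 (SE 0.0345, adjusted p = 0.0820), were not called over all genes in the authors' deposited table. Over all 22 Pcdhb genes of the table, 19 had a positive value in the authors' deposited table.

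**Figure D3:**
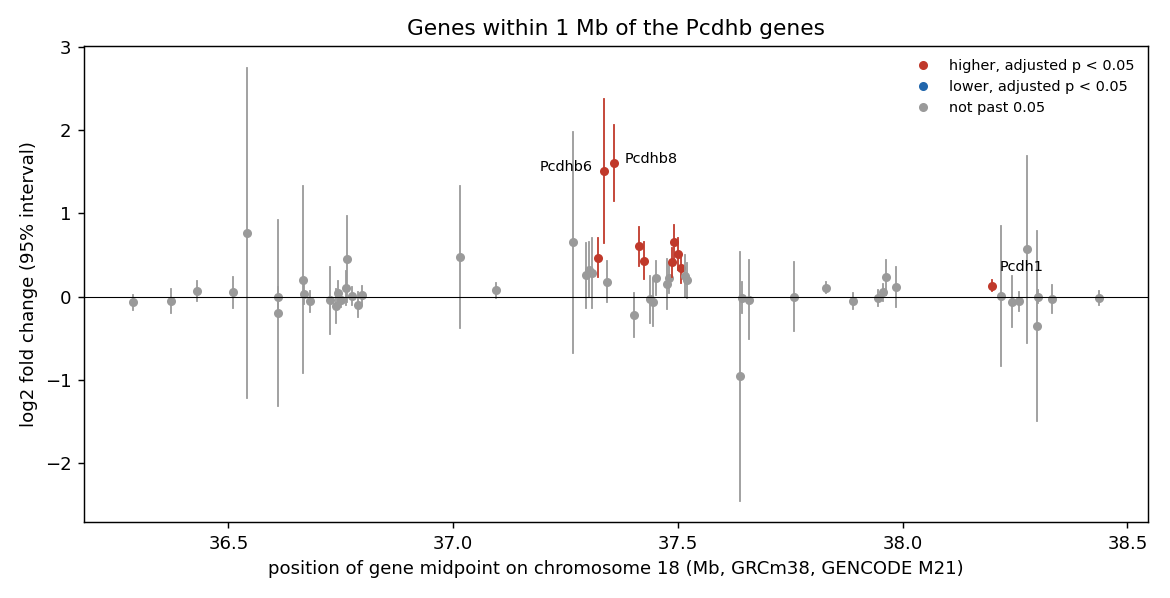
Log2 fold change (labelled knockout over control) of each gene within 1 Mb of the Pcdhb genes, placed at its midpoint on chromosome 18, with 95% intervals from the authors' deposited table. The called genes are 9 Pcdhb genes, up to 1.61 for Pcdhb8, and the unclustered protocadherin Pcdh1 at 0.13.

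Reactive astrocyte genes were higher as a group, with 3 of 24 called (Serpina3n, Fkbp5 at 0.37 and Cxcl10 at 1.61 in the authors' deposited table) and 4 adjusted over the list alone. Their median was 0.13 (limma cameraPR, adjusted p = 1.7e-06, 8.9e-04 at a correlation of 0.05, and 0.0695 with log2 fold changes in place of statistics). Fkbp5 is a glucocorticoid-induced chaperone partner and Cxcl10 an interferon-induced chemokine, and Gfap, the astrocyte filament, stood at 0.14 (SE 0.0470, adjusted p = 0.150). Astrocyte markers in general had a median of 0.03 over 20 genes (adjusted p = 0.692) and microglia markers -0.02 over 22 (adjusted p = 0.614), with no member called. Neocortex markers passed with a median of 0.08 (adjusted p = 8.4e-06), with Stac2 and Cux2, at 0.37, called of 19 and 3 adjusted over the list alone. Without Stac2 that list had an adjusted p of 0.0858, with ranks of the statistics 0.194, and with log2 fold changes 0.236.

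Further lists passed with few or no called members. Endothelial and mural markers had a median of 0.13 (adjusted p = 0.00132, 0.0337 at a correlation of 0.05, and 0.180 with log2 fold changes in place of statistics) with 0 of 24 called. Meningeal and fibroblast markers had a median of 0.27 (adjusted p = 0.00795, and 0.0650 at a correlation of 0.05) with 0 of 18 called. Fewer than 5 of these 18 genes had an SE of at most 0.25, so that setting left the list out. Interferon-stimulated genes had a median of 0.09 (adjusted p = 0.0181, and 0.172 at a correlation of 0.05), with Cxcl10 the 1 of 32 called. That call was also lost without Cxcl10 (adjusted p = 0.0600) and with an SE of at most 0.25 (adjusted p = 0.0664). Antigen presentation and complement genes had a median of 0.09 (adjusted p = 0.0311, and 0.172 at a correlation of 0.05) with 0 of 20 called. That call was also lost with log2 fold changes in place of statistics (adjusted p = 0.581) and without the strongest member, Tap2 (adjusted p = 0.0711). Adjusted over the list alone, these lists had no called member apart from Cxcl10. Values are from limma cameraPR on the authors' deposited table.

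**Figure D4:**
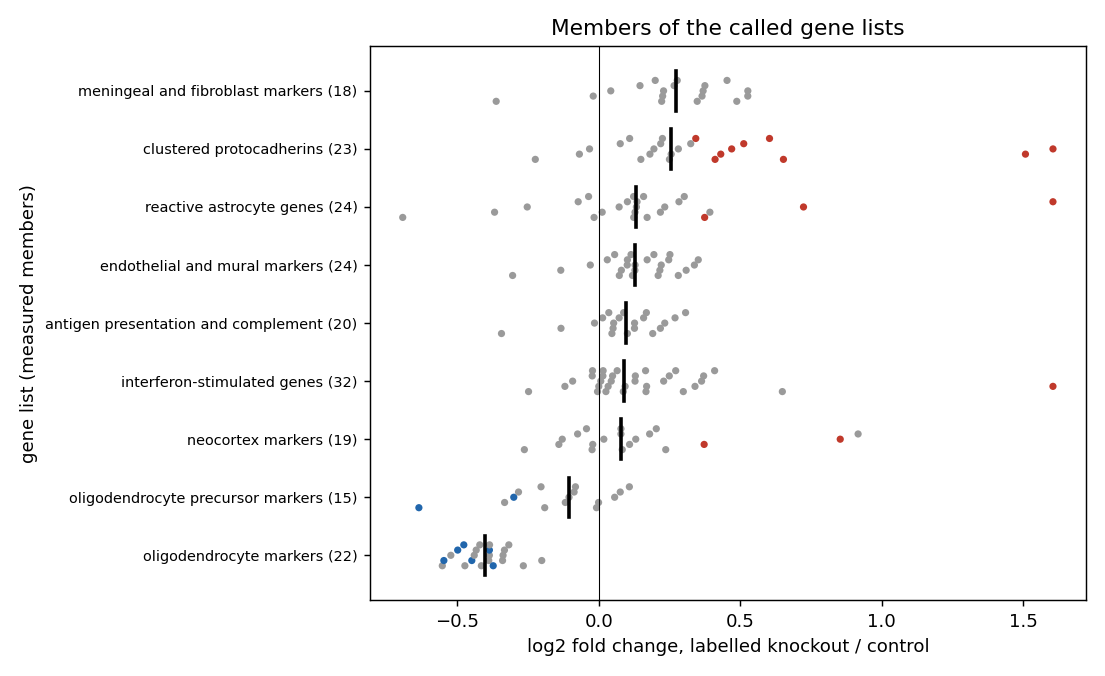
Log2 fold changes (labelled knockout over control) in the authors' deposited table of the members of the 9 called lists, with a black line at each median and coloured points past an adjusted p of 0.05 (red higher, blue lower). The oligodendrocyte markers all lie below 0, with a median of -0.40.

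The other 35 lists did not pass limma cameraPR. Markers of dentate granule cells (17 genes, median -0.03, adjusted p = 0.362), of CA1 (11, -0.02, 0.832) and of CA2 and CA3 pyramidal cells (16, -0.01, 0.362) were among them. The dentate markers Lct, at 0.86 (SE 0.105, adjusted p = 7.3e-13), and Dsp, at 0.34 (SE 0.0738, adjusted p = 6.7e-04), were called higher in the authors' deposited table, and the CA2 and CA3 marker Bok, at -0.28 (SE 0.0783, adjusted p = 0.0260), lower. Adjusted over the list alone, 4 dentate markers were higher and 2 lower, and 1 marker of CA2 and CA3 was higher and 3 lower. Ionotropic glutamate receptors (17 genes, median 0.02, adjusted p = 0.692), GABA receptors (14, -0.02, 0.406) and synaptic vesicle genes (29, -0.01, 0.426) had no called member over all genes, and adjusted over the list alone 2 GABA receptor genes were lower. Imprinted genes had 2 of 38 called, the noncoding Rian at 0.45 (SE 0.0583, adjusted p = 1.2e-11) and Mirg at 0.46 (SE 0.134, adjusted p = 0.0403) in the authors' deposited table, and 3 adjusted over the list alone. Penk, the enkephalin precursor and a striatum marker, was higher by 1.14 (SE 0.249, adjusted p = 8.9e-04), and Syndig1l by 0.36 (SE 0.105, adjusted p = 0.0491), the 2 of 17 striatum markers called in the authors' deposited table, with the list at a median of -0.02 (adjusted p = 0.794). Choroid plexus and ependymal markers had a median of -0.24 over 24 genes, 23 of them negative, with none called (adjusted p = 0.0893). That list did pass with a correlation of 0 (adjusted p = 0.0430), with ranks (0.0145), with log2 fold changes (0.00452) and with an SE of at most 0.25 (0.0277, 5 members). Median, mean and test differed in sign for 7 of the lists that did not pass.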

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

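The other sets of genes, Bonferroni, the rescaled statistics and every setting of the list test were chosen after seeing the data, and the fold of 1.5 and the adjusted p of 0.1 beforehand. The 257 calls, 64.6% of them higher, became 67 (83.6% higher) with a fold of at least 1.5 and 79 (81.0% higher) with Bonferroni. The counts fell by construction of a stricter threshold, while why the share of higher calls moved was not tested. The other settings gave 250 to 367 calls and 59.1 to 64.3% higher. With the fold direction turned round, these shares would be 35.4% for the main setting, 16.4% with the fold, 15 of the 79 calls with Bonferroni and 35.7 to 40.9% in the others. Sumo2 passed no threshold in the 5 other settings in which it was tested, and its own SE of 0.252 kept it out of the setting with an SE of at most 0.25. The 9 list calls ranged from 6 to 11. Oligodendrocyte markers and clustered protocadherins were called under all 7 other settings of the list test. The oligodendrocyte precursor, reactive astrocyte, and endothelial and mural lists lost the call only with log2 fold changes in place of statistics (adjusted p = 0.218, 0.0695 and 0.180). The cause was not tested. Neocortex markers lost the call with ranks, with log2 fold changes and without Stac2, and choroid plexus and ependymal markers gained one with a correlation of 0 (adjusted p = 0.0430), ranks, log2 fold changes and an SE of at most 0.25. Calls as lower were also gained by immediate early genes (0.0150 with ranks, 0.0213 without the strongest member), interneuron markers (0.0343 and 0.0452 in the same settings) and neighbours of Sumo2 (0.0382 with a correlation of 0). Blood cell markers gained a call as higher (0.0320 with log2 fold changes). Among named genes, 20 calls were lost with Bonferroni, and Olig2 and Iyd gained one in some settings. No paired analysis was possible because the columns carry no replicate numbers from the labels. Planned but not run, since they need values per sample, were other normalizations, tools, filters and pseudocounts, leaving out each library, an estimated correlation, fry, and the comparison of an own fit with the deposited one. Depth per library was not analysed here, so what it limits is seen only in the SE: at the median SE, a log2 change of 0.184 is the smallest whose 95% interval excludes 0.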

Other observations

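Of the tests below, those on shared windows were written before their result was seen. The regional medians, the random lists, the scatter of the markers, the thalamus comparison and the turned direction were chosen after.

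Counts follow for 6 gene families picked after the called genes were seen, so no test is given for them. Of 30 measured histone genes 4 were called higher and 22 had a positive value (median log2 fold change 0.25), with Hist1h1c at 0.47 (SE 0.103) in the authors' deposited table. Of 43 collagen chains 5 were called higher and 28 had a positive value (median 0.06), with Col12a1, a fibril-associated collagen, at 0.92 (SE 0.172). For comparison, meningeal and fibroblast markers had a median of 0.27 (16 of 18 positive) and endothelial and mural markers of 0.13 (21 of 24 positive). Of 5 neurofilament and peripherin genes, Nefl at -0.20 (SE 0.0350) and Nefm at -0.17 (SE 0.0406) were called lower and Prph at 0.96 (SE 0.267) higher in the authors' deposited table. That family had a median of -0.10, with 2 of 5 positive. In the remaining 3 families, as in the histone and collagen families, a few genes were called higher and none lower. These 3 were semaphorins, netrins, Slits and Robos (3 of 31 called, 13 positive, median -0.02), ADAMTS proteases (2 of 18, 10 positive, median 0.01) and Zfp genes (2 of 346, 169 positive, median -0.00427).

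The largest rises among all called genes in the authors' deposited table, singled out after their values were seen, were Morc1 at 3.37 (SE 0.548, 10.4-fold), Tcfl5 at 2.74 (SE 0.407, 6.68-fold) and Ltbp2 at 2.21 (SE 0.384). Morc1 and Tcfl5 are known mainly from male germ cells, but neither was in the germline list. Of the 26 genes of that list, 15 were measured and none was called. The list did not pass (median 0.10, limma cameraPR, adjusted p = 0.406, and 0.0535 with log2 fold changes in place of statistics).

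Sumo2 was not lower in the group labelled knockout, while the adjacent Hn1 was. Reads shared with other genes are argued against for Hn1 by a share of 4.68% of its windows. A common fall of the region is argued against by a median log2 fold change of -0.0134 over the other genes within 1 Mb. A median cannot show regional causes that change single genes. For Sumo2, 29.1% of windows are shared, between the bounds of 10 and 50% set for this test, so shared reads stay open. Whether counting dropped or kept such reads cannot be told from the share, and most windows of Sumo2 are not shared. A turned fold direction also stays open, since the reversed interval of Sumo2 runs from -0.919 to 0.0693. The whole of that interval lies above a bound of -1 set earlier. After the value was seen, that bound was dropped as too strict for a deletion in part of the cells. An effect of the recombined allele on Hn1 is a hypothesis of genotype that was not tested.

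Pcdhb genes were higher together. Shared reads are argued against by a median of 5.47% shared windows over the called genes. A common rise of the region is argued against by a median of -0.0126 over the neighbouring genes. A general rise of genes measured equally poorly is argued against, since 0 of 10000 random lists matched on SE reached the Pcdhb median of 0.30, the highest being 0.15. The drawn genes were treated as independent, which Pcdhb genes may not be, and the draws come close to repeating the list test. A genotype effect on this cluster remains a hypothesis, as batch, sex and litter are not in the labels. None of the 6 measured sex-linked genes was called. Their median log2 fold change was -0.00241, with quartiles of -0.0658 and 0.102 (limma cameraPR, adjusted p = 0.923). Fewer than 5 of these 6 genes had an SE of at most 0.25, so these values cannot exclude an imbalance of sexes.

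Oligodendrocyte markers were lower together. A general fall of genes measured equally well is argued against, since 0 of 10000 random lists matched on SE reached the median of -0.40, the lowest being -0.16, although the drawn genes were treated as independent and the draws come close to repeating the list test. Less white-matter-rich neighbouring tissue in the dissection may have contributed and cannot be told apart. Thalamus markers had a median of -0.0737 with an interquartile spread of 0.355. Of these 15 markers, 10 were negative and 5 positive (limma cameraPR, adjusted p = 0.106). Plekhg1, at -0.58 (SE 0.120, adjusted p = 3.0e-04) in the authors' deposited table, was the 1 called thalamus marker. Other lists of neighbouring tissue went both ways (medians of -0.24 for choroid plexus and ependymal, 0.08 for neocortex and 0.27 for meningeal and fibroblast markers). Fewer mature oligodendrocytes with unchanged RNA per cell also cannot be told apart from a common fall per cell. The share of variance between markers beyond their SEs (I2) was 0%, but their scatter (Q = 9.44) lay below the lower 95% bound of 10.3 for independent errors, as errors shared between markers or SEs that are too large would both give, so a low I2 decides nothing (this condition was added after the value was seen).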
